A study of Mus musculus with 6 samples.

How the data were processed

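The series holds 6 libraries of bone marrow mesenchymal stem cells from mice, 3 of genotype Grx2 wild type and 3 of genotype Grx2 knockout, grouped by the genotype in the labels. Per the labels' protocols, total RNA was taken up in TRIzol and libraries were made with the VAHTS Universal V6 RNA-seq kit. The authors deposited a table of FPKM values, fragments per kilobase of gene scaled by depth, with 1 column per library and 22984 gene symbols. Per the submitters' processing notes, HISAT2, HTSeq and R 3.2.0 were used with genome build GRCm39; the versions of HISAT2 and HTSeq, the annotation, the filters and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. FPKM corrects for depth and gene length but not for a shift in composition between libraries.

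FPKM values were used as deposited, without further scaling. Because the authors counted whole reads, each value is a whole multiple of what 1 read is worth, and whole reads were recovered in all libraries for 22982 genes (99.99%), within a tolerance of 1e-06 reads. The implied depth was 40797879 to 41794919 reads per library, a difference of at most 2.44%, and listed genes held 99.7% to 99.8% of it. At this depth counting error is small for most tested genes; intervals given for reads cover counting error only. Within groups, chi-square values per gene against sampling noise ran from 3.86 (wild type replicates 1 and 3) to 16.2 (1 and 2) in wild type and from 4.30 (2 and 3) to 22.8 (1 and 2) in knockout, so no library was a copy of another; wild type replicate 2 and knockout replicate 1 stood furthest from their groups. On the first principal component, with 94.5% of the variance, the genotypes separated.

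Genes with a mean FPKM of at least 1 over the 6 libraries were tested (11083 genes). log2(FPKM + 1) values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend), knockout against wild type, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05, and no fold minimum. The choices of test, filter, named genes, gene lists and most alternatives were made before the data were examined. Named genes are Glrx2, the 12 largest changes in each direction among called genes whose groups do not overlap, up to 4 members of each list with the smallest p, and called genes within 5 Mb of Glrx2; some list members that the rule allows are not reported here. Symbols of predicted or RIKEN genes, immunoglobulin and T cell receptor segments and pseudogenes were counted and not named, and sex-linked genes appear only in the check of sex. Gene neighbours came from a RefSeq table of GRCm38.p6, which matched 11066 of the tested symbols; it is another build than the one in the submitters' notes, so no coordinates are given.

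Of 43 gene lists written from textbook knowledge, 37 had at least 5 tested members and were tested with camera at a preset inter-gene correlation of 0.01, which asks whether a list moves relative to the other genes; the results were adjusted over the lists. The test was repeated with a correlation estimated per list and with fry, which asks whether a list's genes move, on balance, one way. Mitochondrial genes appear in the table under RefSeq symbols such as COX1, and were matched by a table of symbols.

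On simulated reads with the wild type means, depth and a dispersion of 0.001546, the same test on 10888 genes recovered 44 of 49 genes changed 1.25-fold, 45 of 46 changed 1.5-fold, 49 of 49 changed 2-fold and 48 of 48 changed 4-fold, with 14 false calls. The simulation gave every gene the same dispersion, kept genes independent and changed few of them. It had no libraries that stand apart, so these rates need not hold for the real data.

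The alternatives changed 1 choice at a time: a pseudocount of 0.1 or 0.01, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, limma without trend or with robust estimation (statmod 1.5.0), array weights, the replicate number as a block, each library left out, a 2-fold minimum and adjusted p under 0.01. Fitting of the array weights stopped before reaching its tolerance. After the data were examined, voom on the recovered reads and a fit without wild type replicate 2 and knockout replicate 1 were added. In fits that left out libraries, the filter was taken over the libraries kept, so the tested members of a list could change. Count tests were not used, since the table holds FPKM. Exact intervals of read ratios are conditional binomial intervals, and differences of list medians have bootstrap intervals from 10000 resamples. Figures were drawn with matplotlib 3.10.9.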

Results

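The series measured messenger RNA in cultured mouse bone marrow mesenchymal stem cells (BMSCs), the adherent stromal cells of marrow that can form bone, fat and cartilage cells. The submitters' design text calls the cells O-BMSCs and does not expand the prefix. There were 3 libraries of Grx2 wild type cells and 3 of Grx2 knockout cells. Glrx2 encodes glutaredoxin 2 (Grx2), a thiol-disulfide oxidoreductase found mainly in mitochondria. The deposited table gave FPKM for 22984 genes. Whole reads worked back from the values put the depth at 40797879, 41203179 and 41435761 reads for wild type replicates 1 to 3. Knockout replicates 1 to 3 had 41794919, 41158685 and 41011482 reads. The labels do not say whether replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries. All values below are means ± SD over n = 3 libraries per group, and log2 fold changes ± SE are knockout over wild type on the log2(FPKM + 1) scale, which understates the change of low genes.

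The design asks how loss of Grx2 alters the transcriptome of these cells. Knockout cells held almost no Glrx2 transcript, and their osteoblast genes, such as Ibsp and Alpl, were lower than in wild type cells, although the list did not pass with an estimated correlation (adjusted p = 0.28). Transcripts of neutrophil granules and the endothelial genes Cdh5, Emcn and Pecam1, present in the wild type libraries, were nearly absent from the knockout libraries. The largest rises included Penk, Comp, Sfrp2 and Lum, while the fixed list of matrix genes had 18 members that rose and 23 that fell and did not pass (camera adjusted p = 0.0856). The lists of targets of the oxidative stress regulator NRF2, cell cycle genes, interferon-stimulated genes and macrophage markers were higher in knockout libraries by camera with a preset correlation. With an estimated correlation no list passed. Of 11083 genes tested, 7465 changed (limma with trend, two-sided, Benjamini-Hochberg adjusted p under 0.05): 4737 were higher and 2728 lower in knockout, and 719 and 392 of these by at least 2-fold. The groups did not overlap for 73.1% of tested genes, where chance gives 10% if the libraries are independent replicates. The labels do not establish this, and replicates drawn from the same culture or pool of a genotype are not excluded. The counts of changed genes therefore do not separate genotype from culture.

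Glrx2 was listed at 3.57, 3.74 and 3.54 FPKM in wild type replicates 1 to 3 (756, 800 and 761 reads) and at 0.0046, 0 and 0 FPKM in knockout replicates 1 to 3 (1, 0 and 0 reads). The wild type to knockout ratio of reads was 2327, with an exact 95% interval of 417 to 91947 that covers counting error only. The log2 fold change was -2.20 ± 0.055 (adjusted p = 3.61e-08). Of 11 tested genes within 5 Mb of Glrx2 in the RefSeq table of GRCm38.p6, 5 rose and 3 fell. These are 72.7% of the neighbours, near the 67.4% of all tested genes that changed, so the counts do not set the region apart. Among them Rgs2, a regulator of G protein signalling, rose by 1.20 ± 0.083, as did Rgs18 (0.48), Rgs1 (0.29) and Aspm (0.38). Ro60, the next gene to Glrx2, fell (-0.86 ± 0.10), as did Cdc73 (-0.20) and Zbtb41 (-0.27, adjusted p = 0.0496 by limma); the remaining gene that rose has no approved name. The groups overlapped for Aspm (adjusted p = 0.0365 by limma), and the calls of Zbtb41, Aspm and Rgs1 did not hold under every alternative, including some that left out 1 library.

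**Figure D1:**
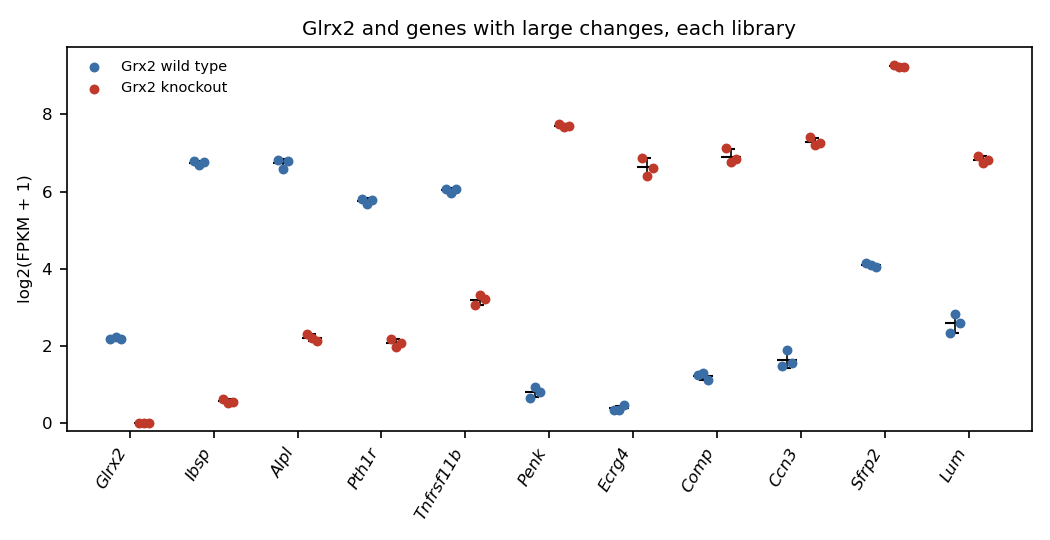
Expression, as log2(FPKM + 1) on the vertical axis, of Glrx2 and 10 genes with large changes, in 3 Grx2 wild type libraries (blue) and 3 Grx2 knockout libraries (red); points are libraries and black marks are the mean ± SD. For each gene shown the groups do not overlap: Ibsp has a mean of 106.6 FPKM in wild type and 0.487 in knockout, and Sfrp2 has 16.2 and 607.5.

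Among the 12 largest rises with non-overlapping groups, Penk, which encodes the precursor of enkephalin peptides, was at 0.742 ± 0.157 FPKM in wild type and 208 ± 7.47 in knockout (6.91 ± 0.067, adjusted p = 4.23e-10). Sfrp2, a secreted modulator of Wnt signalling, was at 16.2 ± 0.521 FPKM in wild type and 608 ± 11.7 in knockout (5.15 ± 0.034). Comp, a cartilage and tendon matrix protein, went from 1.33 to 119 FPKM, Thbs4, a matrix thrombospondin, from 8.18 to 170.2 FPKM, and Lum, a proteoglycan of collagen fibrils, from 5.05 to 113 FPKM. The others were Ecrg4 (6.24), Ccn3 (5.64), Egfl6 (5.26), Abi3bp (4.67), Crabp1 (4.18), Igfbp2 (4.16) and Vegfd (4.02). Of the 12 largest falls, 11 were myeloid or stefin genes and the other was Ibsp. S100a9 and S100a8, the subunits of calprotectin, had log2 fold changes of -8.36 ± 0.33 and -8.10 ± 0.34, and the neutrophil granule genes Ngp, Ltf, Camp and Chil3 had -7.83, -5.99, -5.47 and -5.13. The stefin genes Stfa1 (-7.32), Cstdc5 (-7.17), Cstdc4 (-6.20), Stfa2l1 (-5.73) and Stfa3 (-5.13) are near-identical copies, so the split of reads among them is uncertain.

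Osteoblast genes were lower in knockout libraries, in which neutrophil (median -3.80) and endothelial markers (-1.75) were lower and macrophage markers (0.89) higher. Of 24 tested members, 1 rose, 21 fell and 2 did not pass (2 rose and 21 fell adjusted over the list alone), with a median log2 fold change of -0.88, -0.96 relative to all tested genes (adjusted p = 2.46e-11, and adjusted p = 0.28 with an estimated correlation). Ibsp, which encodes bone sialoprotein, was at 107 ± 3.36 FPKM in wild type and 0.487 ± 0.0589 in knockout, and Alpl, tissue-nonspecific alkaline phosphatase, at 106 ± 8.94 FPKM in wild type and 3.66 ± 0.272 in knockout (adjusted p = 4.41e-09). Pth1r, the parathyroid hormone receptor, went from 53.1 to 3.23 FPKM, and Tnfrsf11b, osteoprotegerin, from 64.3 to 8.18 FPKM. The member that rose was Ogn (0.51 ± 0.12), a small proteoglycan, named after its value was seen. Smooth muscle and myofibroblast genes also fell: of 10, 0 rose, 10 fell and 0 did not pass (0 rose and 10 fell adjusted over the list alone; adjusted p = 5.09e-05, and adjusted p = 0.724 with an estimated correlation). Actg2, gamma smooth muscle actin, was at 255 ± 22 FPKM in wild type and 56.4 ± 18.1 in knockout, lowest in knockout replicate 1 (36.3 FPKM, against 71.4 and 61.4), and Tpm1 and Mylk had -0.65 and -0.92.

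Genes of other mesenchymal fates moved in both directions, and none of these lists passed the list test. Of 16 adipocyte genes, 8 rose, 4 fell and 4 did not pass (8 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.993, 0.997 with an estimated correlation). Apoe fell by 4.82 on the log2 scale while Lpl rose (1.99 ± 0.10). Its median (0.15) and mean (-0.21) differ in sign, with the camera direction higher, but lower with no filter, with the replicate block and without wild type replicate 1 or 3 or knockout replicate 1 or 3. Of 8 chondrocyte genes, 5 rose, 3 fell and 0 did not pass (5 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.958, 0.966 with an estimated correlation). Col2a1 was lower (-1.35 ± 0.04) and Comp higher. Without knockout replicate 1, 2 or 3 the chondrocyte list had 4 that rose and 4 that fell, its median went from 1.04 to 0.093, 0.19 and 0.15, and the camera direction turned lower, as it did with a mean FPKM of at least 5, voom and without both libraries that stand apart. Of 24 stromal surface and niche genes, 9 rose, 11 fell and 4 did not pass (9 rose and 11 fell adjusted over the list alone; camera adjusted p = 0.199, 0.724 with an estimated correlation). Thy1, the mesenchymal surface protein CD90, rose (3.72 ± 0.11), while Mcam (-2.80 ± 0.063) and Cd200 (-3.06 ± 0.1) fell. Of 45 matrix genes, 18 rose, 23 fell and 4 did not pass (19 rose and 23 fell adjusted over the list alone; camera adjusted p = 0.0856, 0.781 with an estimated correlation). Eln, elastin, rose (3.85 ± 0.055) and Loxl2, a collagen crosslinker, fell (-3.10 ± 0.06). The matrix list had a median of -0.25 and a mean of 0.046, and its camera direction was lower. Without wild type replicate 2 it had adjusted p = 0.0234 (range 0.0195 to 0.559 over the 18 alternatives with the preset correlation). Of 25 Wnt pathway genes, 12 rose, 11 fell and 2 did not pass (12 rose and 11 fell adjusted over the list alone; camera adjusted p = 0.518, 0.855 with an estimated correlation). The camera direction was lower, although the median (0.089) and mean (0.037) were above 0. Without knockout replicate 1 the Wnt list had 8 that rose, 11 that fell and a median of -0.088, and without both libraries that stand apart, a fit chosen after the data were examined, the median was -0.029. With median-of-ratios scaling 11 rose and 11 fell, and with quantile normalization 11 rose and 12 fell. Sfrp2 and Lgr5 (2.54) were among those higher and Wnt10b (-3.21) and Ccn4 (-2.42) among those lower. Of 27 TGF-beta and BMP genes, 15 rose, 6 fell and 6 did not pass (15 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.47, 0.781 with an estimated correlation). Bmp4 (1.87) and Tgfb2 (-2.10) are examples. With median-of-ratios scaling 13 of this list rose and 10 fell, and with quantile normalization 14 rose and 11 fell, and its median of 0.24 ran, with 1 library left out, from 0.16 without knockout replicate 2 to 0.44 without wild type replicate 2.

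NRF2 targets and thiol redox enzymes were higher in knockout libraries, in which macrophage markers such as Cd68 (1.55 ± 0.036) and Adgre1 (2.25 ± 0.073) rose as well. Of 26 NRF2 targets, 24 rose, 2 fell and 0 did not pass (24 rose and 2 fell adjusted over the list alone), with a median of 0.98, 0.90 relative to all tested genes (adjusted p = 7.43e-06, and adjusted p = 0.671 with an estimated correlation). Nqo1, a quinone reductase, was at 2.77 ± 0.579 FPKM in wild type and 41.6 ± 5.28 in knockout (3.50 ± 0.12, adjusted p = 1.49e-07), and Hmox1, heme oxygenase 1, at 163 ± 4.41 FPKM in wild type and 459.9 ± 14.2 in knockout (1.49 ± 0.036). Blvrb (1.95 ± 0.057) and Srxn1 (1.46 ± 0.05) rose as well. Of 34 thiol redox enzymes, a list without Glrx2, 24 rose, 5 fell and 5 did not pass (24 rose and 5 fell adjusted over the list alone; adjusted p = 0.021, and adjusted p = 0.724 with an estimated correlation). Sod3 (2.99 ± 0.056), Prdx1 (1.24 ± 0.034) and Cat (1.06 ± 0.039) rose. Gpx3, a secreted glutathione peroxidase named after its value was seen, fell (-4.40 ± 0.17). With a mean FPKM of at least 5 the thiol list had adjusted p = 0.055 (range 9.51e-05 to 0.055 over the 18 alternatives with the preset correlation). Both lists share members with others: 9 of the 27 listed NRF2 targets and 7 of the 34 thiol enzymes are also on another list. Of 23 ferroptosis and iron genes, 8 rose, 9 fell and 6 did not pass (8 rose and 9 fell adjusted over the list alone; camera adjusted p = 0.406, 0.781 with an estimated correlation). Steap3 was higher (2.76), while Trf went from 19.2 to 6.2 FPKM and Ptgs2 from 40.3 to 9.4 FPKM. With median-of-ratios scaling 7 of these rose and 12 fell, and with quantile normalization 7 rose and 13 fell.

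Mitochondrial lists moved little and none passed the list test as planned, but with no filter on low values 5 did, toward higher values: complex I (adjusted p = 0.000197), the other complexes (0.0225), the mitochondrial ribosome (0.00243), iron-sulfur assembly (0.0336) and the tricarboxylic acid cycle (0.0225), with highest adjusted p of 0.559, 0.986, 0.59, 0.559 and 0.787 over the alternatives. Without the filter the median of all tested genes was 0.0032 against 0.085 with it, while the complex I median stayed at 0.135. Of 36 nuclear complex I subunits, 21 rose, 0 fell and 15 did not pass (21 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.0594, 0.724 with an estimated correlation). Ndufs7 (0.38 ± 0.035) and Ndufa13 (0.31 ± 0.032) are examples. Without knockout replicate 1 or 3 the complex I list had adjusted p = 0.0389 and 0.0494, with array weights 0.0424 and without both libraries that stand apart 0.0444 (range 0.000197 to 0.559 over the 18 alternatives with the preset correlation). Of 39 subunits of the other complexes, 17 rose, 0 fell and 22 did not pass (15 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.347, 0.855 with an estimated correlation). Atp5e (0.35) and Cox7c (0.28) rose. With median-of-ratios scaling these counts became 11 rose and 1 fell, and 9 rose and 8 fell. Of 46 mitochondrial ribosomal genes, 22 rose, 1 fell and 23 did not pass (22 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.112, 0.733 with an estimated correlation), including Mrps6 (0.66). Of 24 tricarboxylic acid cycle genes, 14 rose, 3 fell and 7 did not pass (14 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.312, 0.733 with an estimated correlation), including Fh1 (0.31) and Pcx (1.11). With quantile normalization these became 11 rose and 7 fell, and 7 rose and 7 fell. Of 28 iron-sulfur assembly genes, 15 rose, 3 fell and 10 did not pass (16 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.341, 0.724 with an estimated correlation). Fdxr fell (-0.82) and Lyrm4 rose (0.63), and with quantile normalization 9 of the list rose and 5 fell. Of 22 dynamics and mitophagy genes, 9 rose, 6 fell and 7 did not pass (9 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.679, 0.823 with an estimated correlation). Bnip3 was lower (-1.66 ± 0.074) and Pink1 higher (0.69 ± 0.048), and the list median (0.039) and mean (-0.018) differ in sign, with the camera direction lower. With median-of-ratios scaling or quantile normalization 5 of them rose and 8 fell. Of 13 genes of mitochondrial DNA, 1 rose, 3 fell and 9 did not pass (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.154, 0.724 with an estimated correlation). With median-of-ratios scaling 0 rose and 6 fell, without knockout replicate 2 the list had 1 that rose and 6 that fell, and the calls of CYTB, ND4 and ND6 did not hold under every alternative. COX1 was at 4384 ± 80.4 FPKM in wild type and 3609.9 ± 92 in knockout. Some of these genes may share reads with nuclear copies, which was not tested, so their levels are uncertain.

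Genes of the integrated stress response and of glycolysis were lower in knockout libraries, in which the neutrophil (median -3.80) and endothelial markers (-1.75) were lower and macrophage markers (0.89) higher. Of 29 integrated stress response genes, 2 rose, 23 fell and 4 did not pass (2 rose and 23 fell adjusted over the list alone), with a median of -0.60, -0.69 relative to all tested genes (adjusted p = 3.17e-07, and adjusted p = 0.671 with an estimated correlation). Nupr1, a stress-induced nuclear protein, was at 185 ± 17.4 FPKM in wild type and 43.1 ± 2.61 in knockout, and Ddit4, an inhibitor of mTOR signalling, at 81.3 ± 3.91 FPKM in wild type and 22.8 ± 2.87 in knockout; Aldh1l2 (-1.52 ± 0.071) and Cth (-1.05 ± 0.061) fell too. Of 22 glycolysis genes, 4 rose, 15 fell and 3 did not pass (4 rose and 15 fell adjusted over the list alone; adjusted p = 0.000254, and adjusted p = 0.671 with an estimated correlation). Slc16a3, a lactate exporter, went from 79 to 23.5 FPKM, and Hk2, Pfkl and Pfkfb3 had -0.84, -0.89 and -1.08. Of 19 unfolded protein response genes, 4 rose, 8 fell and 7 did not pass (4 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.175, 0.724 with an estimated correlation). Xbp1 was at -0.29 and Herpud1 at -0.49. Of 53 cytosolic ribosomal protein genes, 0 rose, 38 fell and 15 did not pass (0 rose and 38 fell adjusted over the list alone; adjusted p = 3.95e-07, and adjusted p = 0.724 with an estimated correlation), by small amounts: the median was -0.14, -0.22 relative to all tested genes, and Rpl5 and Rps12 had -0.38 ± 0.028 and -0.29 ± 0.03. With quantile normalization 3 ribosomal genes rose and 27 fell.

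Cell cycle, interferon-stimulated and NF-kB response genes were higher in knockout libraries. Of 40 cell cycle genes, 34 rose, 0 fell and 6 did not pass (34 rose and 0 fell adjusted over the list alone), with a median of 0.63, 0.54 relative to all tested genes (adjusted p = 1.88e-05, and adjusted p = 0.724 with an estimated correlation). Pcna, the sliding clamp of DNA replication, was at 98.3 ± 2.67 FPKM in wild type and 239.8 ± 10.2 in knockout, and Mcm4 and Mcm6, subunits of the replicative helicase, had 1.01 ± 0.039 and 1.15 ± 0.046. Of 23 interferon-stimulated genes, 22 rose, 0 fell and 1 did not pass (22 rose and 0 fell adjusted over the list alone; adjusted p = 1.88e-05, and adjusted p = 0.724 with an estimated correlation); Ifi27l2a was at 1.58 ± 0.775 FPKM in wild type and 39.3 ± 2.68 in knockout, and Oas3 and Oasl2 had 2.04 ± 0.087 and 1.74 ± 0.095. Of 22 NF-kB response genes, 15 rose, 4 fell and 3 did not pass (15 rose and 4 fell adjusted over the list alone; adjusted p = 0.0381, and adjusted p = 0.733 with an estimated correlation), including the adhesion molecules Icam1 (2.96 ± 0.091) and Vcam1 (1.82 ± 0.079). Without knockout replicate 1 this list had adjusted p = 0.0537 (range 0.00243 to 0.0537 over the 18 alternatives with the preset correlation). Of 23 senescence-associated secreted factors, 18 rose, 5 fell and 0 did not pass (18 rose and 5 fell adjusted over the list alone; adjusted p = 0.0423, and adjusted p = 0.724 with an estimated correlation), including Icam1 and the growth factor binders Igfbp2, Igfbp3 (3.13 ± 0.11) and Igfbp6 (2.31 ± 0.082). That list lost its call under 5 of 18 alternatives (adjusted p 0.00287 to 0.0865 over the 18 alternatives with the preset correlation). Lists share members: 13 of the 25 listed NF-kB genes and 9 of the 34 listed secreted factors are also on another list. Their calls are therefore not independent. Of 36 autophagy and lysosome genes, 26 rose, 6 fell and 4 did not pass (26 rose and 7 fell adjusted over the list alone; adjusted p = 0.0294, and adjusted p = 0.671 with an estimated correlation). The lysosomal hydrolases Ctsb (0.94 ± 0.029), Ctsd (0.89 ± 0.033) and Hexa (0.74 ± 0.029) rose, and 3 members fell without wild type replicate 1 or 3 or knockout replicate 3, but 9 fell and 21 rose with median-of-ratios scaling or quantile normalization. The list lost its call under 3 alternatives (range 0.000133 to 0.055 over the 18 alternatives with the preset correlation). Macrophage markers such as Cd68 (1.55 ± 0.036) rose in the same libraries.

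The other pathway lists did not pass. Of 16 senescence genes, 8 rose, 3 fell and 5 did not pass (8 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.819, 0.855 with an estimated correlation). Igfbp5 (-4.08) and Igfbp7 (-1.56) were lower and Plau (0.56) higher. The median (0.15) and mean (-0.22) differ in sign, and with median-of-ratios scaling or quantile normalization 4 rose and 6 fell. Of 28 p53 targets, 16 rose, 7 fell and 5 did not pass (16 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.399, 0.855 with an estimated correlation). Rprm (2.23) and Perp (2.13) were higher. Of 27 apoptosis genes, 12 rose, 5 fell and 10 did not pass (12 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.787, 0.855 with an estimated correlation). Bcl2a1b was at -2.58 and Bcl2l1 at 1.02, and with quantile normalization 9 of the list rose and 8 fell. Of 21 cholesterol synthesis genes, 8 rose, 2 fell and 11 did not pass (8 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.843, 0.966 with an estimated correlation). Msmo1 was at 0.44 and Sqle at 0.40, and with quantile normalization 4 of the list rose and 5 fell. With median-of-ratios scaling 5 rose and 3 fell. Without knockout replicate 2 or 3 there were 6 and 5 that rose and 2 that fell, and the list median of 0.047 became -0.012 without knockout replicate 2. Of 20 immediate early genes, 7 rose, 4 fell and 9 did not pass (7 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.828, 0.855 with an estimated correlation). Klf4 was at 1.04 and Jund at -0.62, and with quantile normalization 5 of the list rose and 6 fell.

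**Figure D2:**
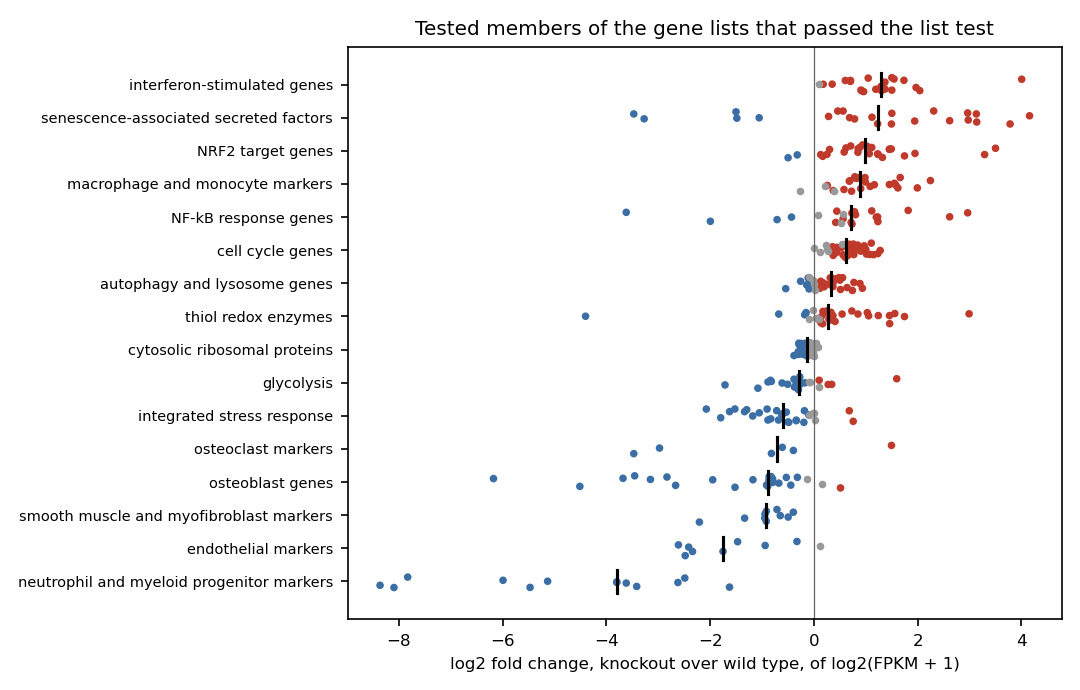
Log2 fold change (knockout over wild type, horizontal axis) of every tested member of the 16 gene lists that passed the list test; red points rose, blue points fell, grey points did not pass, and black bars are list medians. The neutrophil list has a median of -3.80, the osteoblast list -0.88 and the NRF2 list 0.98.

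Markers of other cell types differed between the groups. All 13 tested neutrophil and myeloid progenitor markers fell (13 adjusted over the list alone), with a median of -3.80, -3.89 relative to all tested genes (adjusted p = 2.97e-08, and adjusted p = 0.671 with an estimated correlation). S100a8 was at 328.3, 999.6 and 532.0 FPKM in wild type replicates 1 to 3 and at 1.16, 0.93 and 1.06 in knockout replicates 1 to 3, and Elane, neutrophil elastase, went from 13.5 to 0.00883 FPKM. Of 9 endothelial markers, 0 rose, 8 fell and 1 did not pass (0 rose and 8 fell adjusted over the list alone; adjusted p = 1.79e-05, and adjusted p = 0.671 with an estimated correlation); Cdh5, the endothelial cadherin, was at 5.46 ± 0.658 FPKM in wild type and 0.0539 ± 0.00979 in knockout, and Emcn and Pecam1 went from 4.1 to 0.0054 FPKM and 4.7 to 0.0652 FPKM. Of 24 macrophage and monocyte markers, 21 rose, 0 fell and 3 did not pass (21 rose and 0 fell adjusted over the list alone; adjusted p = 5.09e-05, and adjusted p = 0.724 with an estimated correlation). Adgre1, the F4/80 antigen, was at 24.7 ± 0.614 FPKM in wild type and 122 ± 13.3 in knockout, Cd68 at 99.8 ± 2.1 FPKM in wild type and 295 ± 10.4 in knockout, and Spi1, a myeloid transcription factor, had 1.66 ± 0.058; the abundant lysozyme gene Lyz2, named after its value was seen, was at 1195 ± 77 FPKM in wild type and 2085 ± 359 in knockout. Of 6 osteoclast markers, 1 rose, 5 fell and 0 did not pass (1 rose and 5 fell adjusted over the list alone; adjusted p = 0.0256, and adjusted p = 0.671 with an estimated correlation): Acp5, tartrate-resistant acid phosphatase, fell (-2.98 ± 0.11) and Tnfrsf11a, the receptor RANK, went from 1.76 to 6.77 FPKM. The osteoclast call was lost with median-of-ratios scaling (adjusted p = 0.0714) and quantile normalization (0.0999; range 0.0143 to 0.0999 over the 17 alternatives with the preset correlation).

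**Figure D3:**
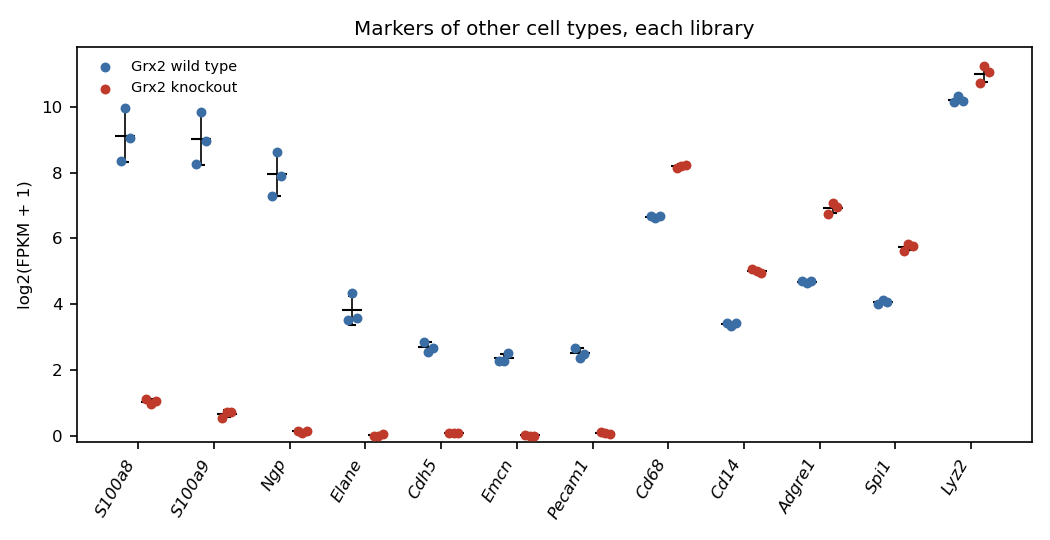
Expression, as log2(FPKM + 1) on the vertical axis, of neutrophil (S100a8, S100a9, Ngp, Elane), endothelial (Cdh5, Emcn, Pecam1) and macrophage (Cd68, Cd14, Adgre1, Spi1, Lyz2) markers in 3 wild type (blue) and 3 knockout (red) libraries; points are libraries and black marks are the mean ± SD. Neutrophil and endothelial genes are low in all knockout libraries, while Cd68 rises from 99.8 to 294.6 FPKM.

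Lists with fewer than 5 tested members had no list test. Skeletal muscle genes varied among wild type libraries: Mylpf was at 2.52, 23.2 and 7.26 FPKM in replicates 1 to 3 and at 0.4 ± 0.167 in knockout, and 3 of 4 tested members fell. The calls of Myog (-1.67, adjusted p = 0.0193) and Tnnt3 (-1.20, adjusted p = 0.0455) did not hold under every alternative. Acta1 (-1.05, limma adjusted p = 0.108) was not called. It passed with array weights (0.0099), with the replicate block (0.0238) and without wild type replicate 1 (0.00226). Of 3 erythroid and megakaryocyte genes, Itga2b (-1.27) and Ppbp (-0.33) fell and Pf4 rose (0.40, adjusted p = 0.0288), a call that did not hold without wild type replicate 1 or 3 or knockout replicate 2 or 3. Of 4 Schwann cell and neural genes, Stmn2 (2.54), Mbp (0.74) and S100b (0.56) rose and Tubb3 fell (-1.94). The tested lymphocyte gene, Ebf1, rose (0.54), and the tested epithelial gene, Krt19, fell (-0.92). Among sex-linked genes, Xist, which is expressed from an inactive X chromosome, was at 10.5, 15.8 and 12.2 FPKM in wild type and at 18.2, 22.8 and 22.0 in knockout replicates 1 to 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 14.3, 15.4 and 15.4 FPKM in wild type replicates 1 to 3. In knockout replicates 1 to 3 they summed to 5.65, 8.82 and 7.60. Transcripts of both kinds were present in all 6 libraries, but their balance differed between the groups. Xist was higher in knockout (0.68, limma adjusted p = 0.00265), and Ddx3y, Eif2s3y and Kdm5d were lower (-0.96, -0.71 and -0.52), without overlap. This difference cannot be told apart from genotype here, and its source was not tested.

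HOX genes, which record position along the body and limb axes, moved in both directions, and the list did not pass. Of 19 tested, 5 rose, 9 fell and 5 did not pass (5 rose and 9 fell adjusted over the list alone; camera adjusted p = 0.0968, 0.724 with an estimated correlation). The median (-0.13) and mean (0.14) differ in sign. Without knockout replicate 1, 2 or 3 the list had 3 members that rose, with medians of -0.25, -0.38 and -0.25. Without wild type replicate 2 the median was -0.0044. Those fits without a knockout library gave camera adjusted p = 0.0246, 0.0175 and 0.0191, toward lower values (range 0.0175 to 0.442 over the 18 alternatives with the preset correlation). In them the filter, taken over the libraries kept, left out Hoxc13 and Hoxd10, which had risen. These had 0.12 and 0.14 FPKM in wild type and 2.07 and 1.86 in knockout. The lower count of rises thus came from the filter, and those adjusted p values rest on a changed set of members. Hoxd13 was at 0.0314 ± 0.0331 FPKM in wild type and 11 ± 1.75 in knockout (3.53 ± 0.10, adjusted p = 6.45e-08), and Hoxd8 (1.73 ± 0.10) and Hoxc13 (1.45 ± 0.08) rose, while Hoxb2 fell (-1.20 ± 0.06). Of 29 HOX genes with at least 100 reads over the 6 libraries, 8 lay wholly higher and 15 wholly lower in knockout, and 6 overlapped. All 6 such HOXD genes were higher, whereas 1 of 11 HOXA, 0 of 4 HOXB and 1 of 8 HOXC genes were.

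**Figure D4:**
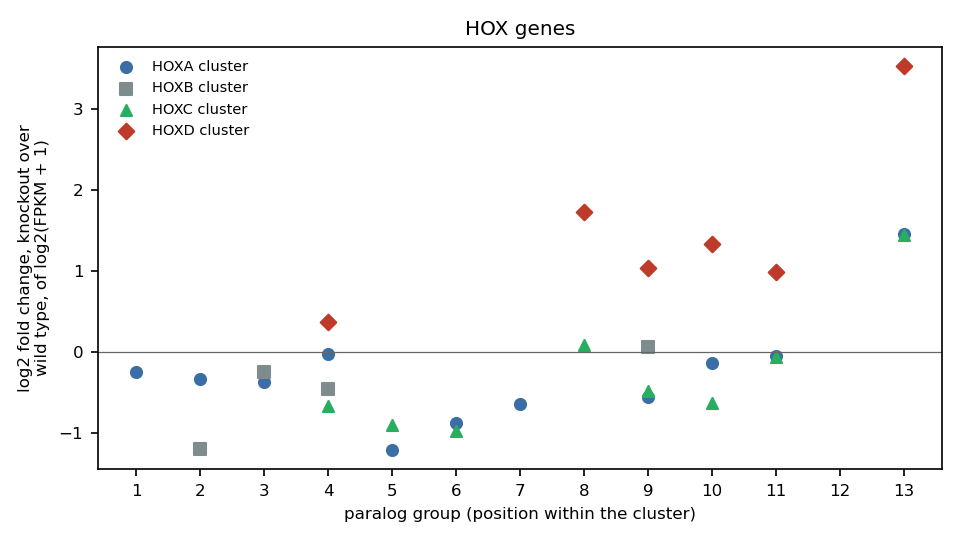
Log2 fold change (knockout over wild type, vertical axis) of 29 HOX genes with at least 100 reads, against paralog group, the position within a cluster (horizontal axis); marker shape and colour give the cluster. Hoxd13, at 3.53, is the largest rise and all 6 HOXD genes lie above 0.

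Of 37 lists tested by camera with a preset correlation, 8 were higher and 8 lower; with an estimated correlation 0 passed, with 1 list, the osteoblast genes, at an unadjusted p under 0.05, and fry called 30. The balance of directions depends on scaling: 63.5% of changed genes were higher with FPKM as deposited, 50.2% with median-of-ratios scaling and 46.5% with quantile normalization, which moved the median log2 fold change of all tested genes from 0.085 by -0.087 and -0.11, so small changes hold only relative to that shift.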

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

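The fits with voom and without both libraries that stand apart were chosen after the data were examined, the others before. Between 6556 (without wild type replicate 3) and 7542 (without knockout replicate 1) genes changed when 1 library was left out. Of these 4190 to 4689 were higher and 2337 to 2853 lower, and 16 to 18 lists changed. The Glrx2 log2 fold change lay between -2.22 and -2.18 in those fits. It was -5.19 with a pseudocount of 0.1, -8.32 with 0.01 and -10.07 with voom. A pseudocount of 0.1 also moved the neutrophil median from -3.80 to -6.94 and the endothelial median from -1.75 to -4.18. A 2-fold minimum left 1111 genes, 719 higher and 392 lower, by construction. Array weights called 9323 genes, voom 7488 and the fit without both libraries that stand apart 7667. Of the 7465 genes called, no gene was called in the opposite direction under any of the 18 refits. Between 82.0% (quantile normalization) and 99.98% (mean FPKM of at least 5) were called again in the same direction, of those still tested.

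With no filter 25 lists changed, with an estimated correlation 0 and with fry 30. With no filter 22984 genes were tested, and the median log2 fold change of the genes that camera compares with fell from 0.085 to 0.0032. The complex I median stayed at 0.135, so for that list the comparison changed and not its members. For the other lists the cause was not tested, and fry asks a different question. The estimated correlation allows for genes of a list moving together, but this does not account for every lost call. How much of the other losses it accounts for was not tested, so they are not evidence of genes moving together. For the autophagy list it was 0.00894, under the preset 0.01, yet the unadjusted camera p went from 0.0111 to 0.0617. A list that did not pass there is therefore not shown to be unchanged. Of the 16 lists called, 11 kept their call under all alternatives with the preset correlation (highest adjusted p = 0.0426), 5 lost it under at least 1, and fry called all 16 in the same direction. With the estimated correlation their adjusted p ran from 0.28 to 0.733. Fry gave the opposite direction for ferroptosis genes (adjusted p = 0.00267) and Wnt genes (adjusted p = 0.00797), whose camera result had not passed; fry does not compare a list with other genes. Of 199 genes computed beside Glrx2, 188 kept their side of the threshold under every setting in which they were tested. The other 11 (CYTB, ND4, ND6, Pf4, Myog, Tnnt3, Acta1, Zbtb41, Aspm, Rgs1 and Prrx1) did not, and 0 reversed. Some genes near the filter, such as Hoxc13, were not tested when a knockout library was left out. At a mean FPKM of at least 5, 32 were not tested. That filter also left no value for Glrx2 and too few members for the endothelial and osteoclast lists.

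Replicate numbers are shared by the groups, but the labels do not pair samples by them. Deviations of same-numbered libraries correlated at 0.107, 0.124 and 0.020, and wild type replicate 3 correlated best with knockout replicate 1 (0.060), so not every library matched its own number. The replicate block gave 7562 changed genes, 4771 higher and 2791 lower.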

Other observations

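The tests of explanations here were chosen after the result was seen. Only the prediction for the proximal limb genes was written before its test, although after the HOX pattern was seen. Quantile normalization as an alternative and the count of changed genes were planned. Of 14 tested genes of tendon and ligament, a set chosen after Tnmd, Comp and Thbs4 were seen, 10 rose and 3 fell, a tally that includes those genes and so tests nothing. Tnmd, a tendon membrane protein, was at 5.52 ± 0.732 FPKM in wild type and 65 ± 3 in knockout, Dcn, the proteoglycan decorin, at 10.1 ± 2.22 FPKM in wild type and 129.8 ± 16.2 in knockout and Prelp at 5.97 ± 0.234 FPKM in wild type and 107 ± 8.66 in knockout, while the tendon transcription factor Scx was lower (-0.45 ± 0.097) and Tnc, tenascin C, was lower (-2.35 ± 0.061). Tbx4, a transcription factor of the hindlimb, was at 1.49 ± 0.202 FPKM in wild type and 9.3 ± 1.13 in knockout, and Pitx1, another hindlimb gene, at 6.95 ± 1.19 FPKM in wild type and 10.5 ± 0.473 in knockout. The forelimb gene Tbx5, under the filter and not tested, also lay wholly higher in knockout (82 reads against 9).

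The count of 7465 changed genes cannot be set against chance by regrouping: 3 libraries against 3 make 10 splits, so a share of splits under 0.05 is out of reach. The real split was the 1 split with so many genes, and the highest of the others called 0 genes. Every other split puts both genotypes in both groups, so the difference between genotypes becomes spread within groups. Few calls there were fixed in advance, and the 0 gives no rate of false calls.

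Osteoblast genes were lower in knockout cells (21 of 24 fell). Dilution of stromal RNA by RNA of other cells would lower stromal genes together, but of 18 tested stromal surface and niche genes, leaving out those taken from general knowledge as macrophage-expressed, 7 rose (Thy1, Pdgfra, Ly6a, Kitl, Angpt1, Grem1 and Prrx1, the last not after quantile normalization). Because these 7 rose, dilution alone does not give this pattern. Since 8 fell, among them Mcam (-2.80), Cd200 (-3.06) and Nt5e (-1.94), a share of dilution is not excluded. Scaling between libraries was taken, after the result was seen, to end the call or raise the median above -0.44. The median was -0.89 after quantile normalization and the list kept its call with the preset correlation. That call is lost with an estimated correlation (camera adjusted p = 0.28 without that normalization). The outcome could hardly differ, since quantile normalization moved the median of all tested genes by -0.11. The values show only that this shift was small beside the fall of the list. A change of the stromal cells themselves with genotype, or a different makeup of stromal cells at culture, may account for the pattern, and neither was tested.

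Neutrophil and endothelial genes were lower and macrophage genes higher in knockout libraries, list calls that are lost with an estimated correlation (adjusted p = 0.671, 0.671 and 0.724). A lower share of stromal cells would raise the markers of every other cell type alike, but the macrophage median lay 4.69 above the neutrophil median (bootstrap 95% interval 4.22 to 6.98, 10000 resamples). The interval covers the spread over marker genes and not the spread between libraries. Those genes move together (estimated correlation 0.96 for neutrophil and 0.598 for macrophage markers). The opposite signs were known when the test was chosen. One candidate source is a single population of neutrophil-lineage cells in the wild type cultures: the log2 ratios between wild type replicates 2 and 1 had a median of 1.46 and an SD of 0.284 over 13 neutrophil genes. The SD alone does not set them apart, since macrophage markers had an SD of 0.293, endothelial markers 0.150 and osteoblast genes 0.169. The medians of those lists were 0.11, -0.25 and -0.11. Endothelial markers thus did not follow the neutrophil genes between these 2 libraries. Whether the genotype or the preparation of the cultures sets these cells apart was not tested.

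Of 9 HOX genes in paralog groups 10 to 13, 5 lay wholly higher and 1 wholly lower in knockout, against 3 and 14 of 20 in groups 1 to 9. All 6 HOXD genes with at least 100 reads lay wholly higher whatever their group. Outside HOXD, the wholly higher genes were Hoxa13 (1.46) and Hoxc13 (1.45), while Hoxc10 was wholly lower (-0.63) and Hoxa10, Hoxa11 and Hoxc11 overlapped. All 14 wholly lower genes of groups 1 to 9 lay outside HOXD. Direction thus differed with position outside HOXD too, on few genes, and within HOXD it did not. Counting error would leave the Hoxd13 read ratio near 1, but 3510 reads against 10 give a ratio of 349.5 with an exact 95% interval of 189.8 to 729.5. Hoxd13 was picked as the largest HOX rise, so this outcome was fixed in advance. It covers that gene alone and not the other genes of the pattern. If knockout cultures came from a more distal skeletal position, proximal limb genes would be lower, and the 5 tested had a median log2 fold change of -1.18: 4 fell (Irx3 -2.27, Irx5 -1.64, Shox2 -1.18 and Meis1 -0.29) and Meis2 rose (0.71). A difference in skeletal source between the groups may therefore contribute, alone or with an effect of genotype on these genes, which was not tested.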
